A study of Mus musculus with 24 samples.

How the data were processed

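Gene expression was measured with 1-colour Affymetrix mouse arrays in 24 samples. They were whole livers and cultured primary hepatocytes of 4 genotypes, with 3 arrays in each of the 8 groups. Per the labels, all mice were 8-week-old males. Controls carried the floxed NEMO gene without the knockout, and the floxed NEMO and KEAP1 genes were deleted in hepatocytes with a Cre transgene under an albumin and alpha-fetoprotein promoter. Per the labels' protocols, hepatocytes were released from the liver by perfusion with collagenase, left to adhere in medium with serum until the next day and then given fresh medium.

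The authors deposited log2 expression values, 1 per probe set and array, made with RMA per the submitters' processing notes. The version of RMA, its software and options, and whether all arrays were processed together are not given in the sources used here. The log2 scale was read from the values, which ran from 0.51 to 13.62 with array medians between 4.04 and 4.23, so no other scale was tried. No array scan dates or slide identities were among the files, so no batch could be tested. For arrays there is no read depth, and 3 arrays per group limit the precision. Xist lay between 2.00 and 2.98 on the 22 arrays where it was low, which serves as a guide to the background, and fold changes that start from such levels are understated.

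The file held 35556 probe sets. The platform annotation paired 21218 of them with 1 gene symbol and 1881 with several, and did not list 12457. Only probe sets with 1 symbol were used. Symbols were checked through their Entrez identifiers against a RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols and left 33 without a match. A gene with several probe sets, as 1386 had, was represented by the probe set with the highest mean over all arrays. This gave 18820 genes, and no filter on low values was applied.

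Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, and adjusted with the Benjamini-Hochberg method over the 18820 genes. A gene was called at an adjusted p under 0.05. Comparisons within a tissue used the 12 arrays of that tissue, so that all 4 genotypes shared an estimate of the spread. They were NEMO knockout, KEAP1 knockout and double knockout against control, the double knockout against each single knockout, and the interaction, which is the double knockout minus both single knockouts plus control. Differences between tissues (the change in liver minus the change in hepatocytes) and the control hepatocytes against control liver used all 24 arrays. The 16 comparisons were each adjusted alone. Whether replicate numbers pair the arrays was read from the correlation of residuals from the group means. Liver controls and liver double knockouts with the same number had r = 0.115, 0.136 and 0.23, all above 0.1, so the fit with the number as a block is given beside that comparison. The pair of 0.23 joins 2 arrays in doubt. Residuals of 3 arrays from their mean sum to 0, so the 3 correlations are not independent and do not establish a pairing. In the titles the number also goes with a code (05, 07 or 09) whose meaning is not given. Changes are log2 fold changes ± the standard error of the fit, with n = 3 arrays per group. Without the 4 arrays in doubt the control and double knockout groups of each tissue held 2 arrays each.

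A set of 35 gene lists with 664 symbols was fixed, of which 593 symbols were measured. They covered NRF2 targets, the pentose phosphate pathway and NADPH supply, glutathione, NF-kB targets and chemokines, death receptor signalling, p53 targets, cell cycle, extracellular matrix and fibrosis, hepatocyte identity, bile acids, cytochrome P450 enzymes, lipogenesis, cholesterol synthesis, fatty acid oxidation and PPARalpha targets, gluconeogenesis and glycogen, and the urea cycle. They also covered acute phase proteins, the interferon response, MHC class II, the unfolded protein response, proteasome subunits, autophagy and lysosome, metallothionein and iron handling, oncofetal genes, male-biased genes, clock genes, and dedifferentiation and culture stress. Markers of cholangiocytes, stellate cells, macrophages, neutrophils, T and natural killer cells, B cells, endothelium and erythroid cells made up the rest. The 34 lists with at least 5 measured genes were tested with limma's camera with a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, and again with a correlation estimated from the arrays. They were also tested with fry, which asks whether the genes of a list move one way on balance and does not compare them with other genes. For single members the count adjusted over the list alone is given beside the count over all genes. Some genes belong to several lists.

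Correlations between changes were computed over the 18820 genes for pairs of comparisons that share no array. Genes are not independent replicates, so these carry no p-value. The genes named were those of the targets (Ikbkg, Keap1) and of NRF2 (Nfe2l2). In the NEMO, KEAP1 and double against NEMO comparisons of each tissue they were also the 10 called genes with the largest rise and the 10 with the largest fall whose 3 arrays of one group all lay above the 3 of the other. In the other comparisons the rule took 5 and 5. Of each list, up to 4 called members with the largest change were named, or up to 2 members with their values where none was called. Names of predicted genes were left out. The design, the lists, this rule and the alternatives were fixed before the data were examined.

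The fitting steps were tested on simulated arrays for the 18820 genes, with a few genes changed by known amounts. For NEMO knockout minus control in liver, 21.2%, 82.1% and 95.5% of genes changed by 0.5, 1 and 2 on the log2 scale were recovered, with 9 unchanged genes called. In hepatocytes the shares were 31.3%, 80.6% and 97.0%, with 7 unchanged genes called. For the difference between tissues they were 7.6%, 61.2% and 90.9%, with 4. A list shifted by 0.5 was found in all 3 simulations by camera with the preset correlation, and 0 other lists were called. The noise of each gene was drawn independently of the other genes. The simulations therefore do not show how often lists of correlated genes are called wrongly.

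The results were also computed with no intensity trend, the replicate number as a block, a filter on dim probe sets, equal medians, a new quantile normalization, array weights, the mean of all probe sets of a gene, all 24 arrays in one fit, only the groups compared, a change of at least 1 as well, and leaving out each array in turn. After the data were seen, 4 arrays were put in doubt and the genes called in each comparison were also counted without them. They are the array labelled liver control 3, liver double knockout 3, hepatocyte control 1 and hepatocyte double knockout 3. Other splits of the samples into groups of the same sizes were counted, with at most 100 drawn. Probe sets with no symbol or several were tested apart and are not named.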

Results

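Whole liver and cultured primary hepatocytes were profiled from control mice and from mice lacking NEMO, KEAP1 or both in hepatocytes. NEMO, encoded by Ikbkg, is the regulatory subunit of the kinase complex that activates NF-kB. KEAP1 directs the transcription factor NRF2, encoded by Nfe2l2, to degradation, and NRF2 drives antioxidant and detoxification genes. Each of the 8 groups held 3 arrays, with array medians between 4.04 and 4.23 on the log2 scale. The first principal component took 35.9% of the variance of the liver arrays and 30.1% of that of the hepatocyte arrays.

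Of the 24 arrays, 4 went against their label or stood apart from their group. On the array labelled liver control 3 the NRF2 target Nqo1, a quinone reductase, was at 9.17, against 4.71 and 5.37 on liver controls 1 and 2 and 9.25 to 9.36 on the liver double knockouts. Slc7a11, the cystine importer, was at 9.29 there, against 2.63 and 2.42. Liver double knockout 3 carried the fat cell transcripts Adipoq at 7.17 and Ucp1 at 6.74 and the bile duct keratin Krt7 at 7.81, while Adipoq was at most 2.76 on every other array. Hepatocyte control 1 and hepatocyte double knockout 3 had Xist, the transcript of the inactive X chromosome, at 9.65 and 9.76 and the Y-linked Eif2s3y at 2.51 and 2.71, although the labels give male mice. On the other 22 arrays Xist lay between 2.00 and 2.98 and Eif2s3y between 6.74 and 7.82. The number of genes called in each comparison is therefore also given without these 4 arrays, a choice made after the data were seen. For the NRF2 targets in liver that choice is not independent, because the array labelled liver control 3 was doubted for its NRF2 target values.

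The deleted genes were read first, as a check of the labels. Ikbkg lay between 6.14 and 6.26 in NEMO knockout livers and between 6.18 and 6.47 in double knockout livers. It was 6.86 and 6.81 on liver controls 1 and 2, 6.40 on the array labelled liver control 3, and 6.96 to 7.20 in KEAP1 knockout livers. Its change was -0.47 ± 0.13 in NEMO knockout liver against control (n = 3 per group, adjusted p = 0.0982) and -0.61 ± 0.12 without the 4 arrays in doubt (adjusted p = 0.00634). In hepatocytes Ikbkg fell by 0.55 ± 0.12 in the double knockout against control (adjusted p = 0.0086) and by 0.80 ± 0.12 against the KEAP1 knockout (adjusted p = 0.00354). It was -0.29 ± 0.12 in the NEMO knockout (adjusted p = 0.177). Keap1 fell by 0.71 ± 0.14 in double against NEMO knockout hepatocytes (adjusted p = 0.0141), a call lost without NEMO knockout 2, double knockout 1 or double knockout 2 (adjusted p = 0.0722, 0.0504 and 0.0629). It was -0.24 ± 0.14 in KEAP1 knockout hepatocytes (adjusted p = 0.505) and -0.55 ± 0.15 in KEAP1 knockout liver (adjusted p = 0.617, and 0.0358 at -0.66 ± 0.16 without the arrays in doubt). Where the probes lie relative to the deleted exons is not given in the sources used here, so these levels are a weak check. Nfe2l2 rose with NEMO loss, by 1.10 ± 0.11 in liver (adjusted p = 0.000949) and by 0.73 ± 0.15 in hepatocytes (adjusted p = 0.00853). In the double knockout it was lower than in the NEMO knockout in both, by -0.93 ± 0.11 (adjusted p = 0.004) and -0.90 ± 0.15 (adjusted p = 0.0049).

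**Figure D1:**
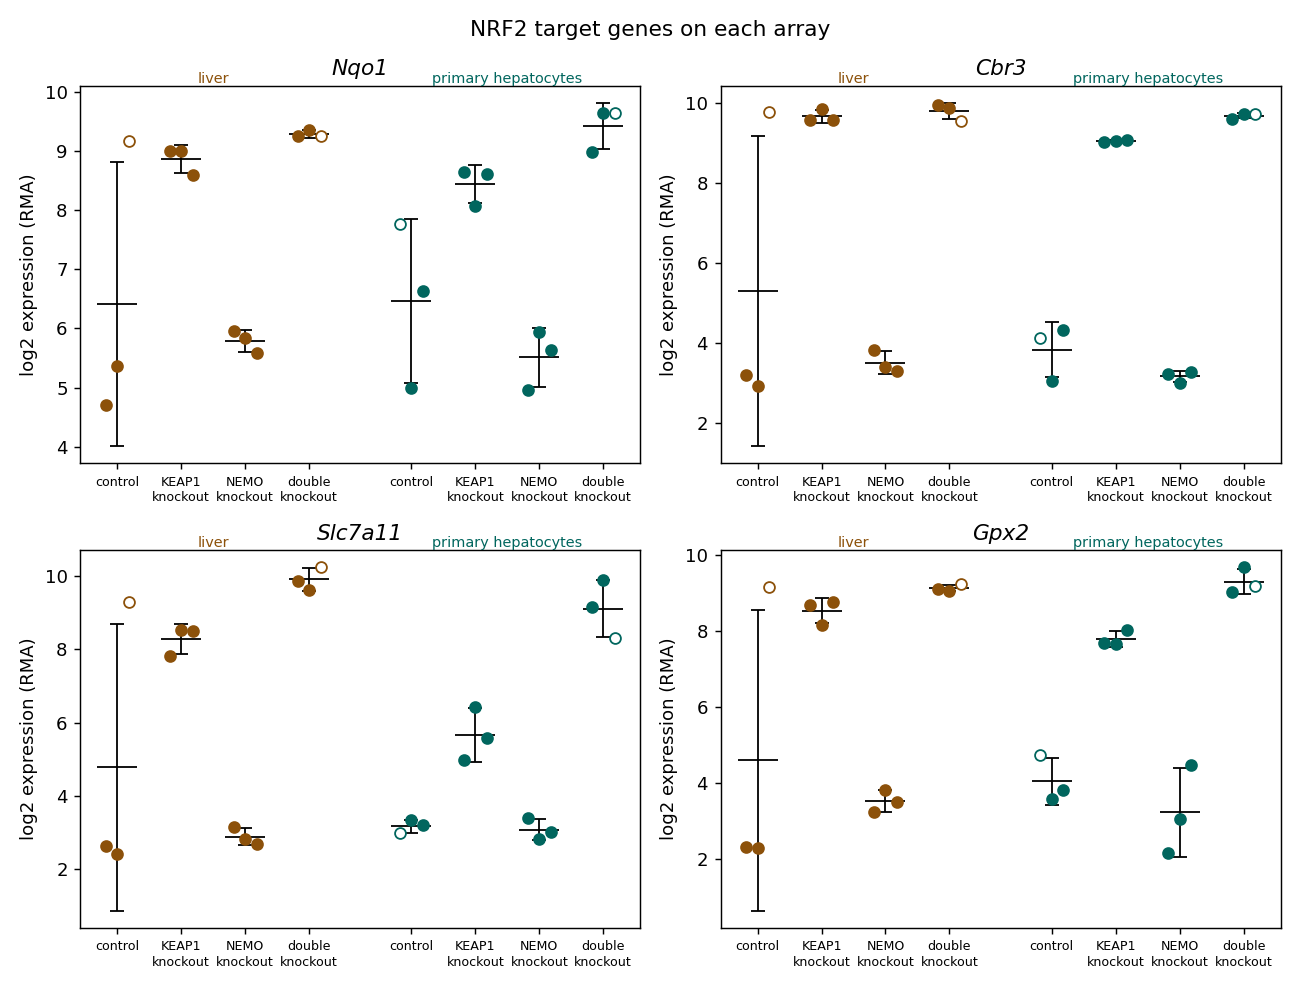
Expression of the NRF2 targets Nqo1, Cbr3, Slc7a11 and Gpx2 (log2 RMA values, vertical axes) on each array of the 8 groups (horizontal axes). Points are arrays, open points the 4 arrays in doubt, and bars the mean ± SD of the 3 arrays of a group. Cbr3 lies between 9.02 and 9.94 on all KEAP1 and double knockout arrays and at 9.76 on the array labelled liver control 3.

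NEMO loss in liver raised 9 of 25 cell cycle genes and 3 of 15 p53 targets (adjusted p = 0.344 and 0.124 with an estimated correlation, with which 0 lists were called in this comparison). Akr1c18, a progesterone-metabolising reductase, rose by 4.40 ± 0.27 (n = 3 per group, adjusted p = 2.47e-05) and Gldn, the gene of gliomedin, by 2.98 ± 0.20 (adjusted p = 3.49e-05). D17H6S56E-5 rose by 3.75 ± 0.65, Prelid2 by 3.19 ± 0.41, Atp6v0d2, a subunit of the vacuolar proton pump, by 2.61 ± 0.33, Mybl1 by 2.61 ± 0.46 and Ckap2, a microtubule protein of dividing cells, by 2.71 ± 0.51. Among genes that fell, Cyp7b1, an oxysterol hydroxylase of bile acid synthesis, changed by -2.37 ± 0.35 and Dio1, a deiodinase of thyroid hormone, by -1.56 ± 0.28. Rarres1 (-1.91 ± 0.26), B3galt1 (-1.66 ± 0.32), Angptl8, a regulator of triglyceride clearance (-1.27 ± 0.17), Aspg (-1.25 ± 0.21), Extl1 (-1.18 ± 0.20), Mpv17l (-1.17 ± 0.18), Capn8 (-1.16 ± 0.19) and the carboxylesterase Ces2a (-1.16 ± 0.18) fell as well. The adjusted p-values of these 15 genes other than Akr1c18 and Gldn lay between 0.00519 and 0.0309. In all, 251 genes were called, 191 higher and 60 lower.

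In NEMO knockout liver 9 of the 25 measured cell cycle genes rose and 23 did when adjusted over the list alone, with a median change of 1.48 (camera adjusted p = 3.19e-22, but adjusted p = 0.344 with an estimated correlation). Ccnd1, the gene of cyclin D1, rose by 2.98 ± 0.33, Ccna2 by 2.72 ± 0.57, Ccnb2 by 2.42 ± 0.41 and Cdc20 by 2.41 ± 0.45. Of 15 p53 targets 3 rose, and adjusted over the list alone 12 rose and 1 fell (camera adjusted p = 1.03e-09, adjusted p = 0.124 with an estimated correlation). They were the cell cycle inhibitor Cdkn1a at 1.52 ± 0.25, the death receptor Eda2r at 1.50 ± 0.20 and the DNA polymerase Polk at 0.91 ± 0.16. Stellate cell markers had a median change of 1.24, with 2 of 18 called (Cygb 1.81 ± 0.39, Reln 0.93 ± 0.14) and 16 adjusted over the list alone. Matrix genes had a median of 1.09, with 2 of 27 called, the proteases Mmp13 (2.16 ± 0.33) and Mmp14 (1.15 ± 0.20), and 19 adjusted over the list alone. Macrophage markers had a median of 0.76, with 2 of 21 called, Gpnmb (2.95 ± 0.60) and the glucan receptor Clec7a (1.90 ± 0.35), and 11 adjusted over the list alone. Camera's adjusted p was 3.27e-13, 7.53e-15 and 5.22e-09 for these 3 lists, and each had an adjusted p = 0.344 with an estimated correlation.

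Other lists were tested in the same livers. Of 21 dedifferentiation and culture stress genes 3 rose, Tubb6 (2.24 ± 0.40), Jun (1.55 ± 0.25) and Tubb2a (1.17 ± 0.20), and 14 did adjusted over the list alone (camera adjusted p = 6.61e-13). Of 19 oncofetal genes 4 rose and 6 did adjusted over the list alone (camera adjusted p = 1.64e-06), Golm1 (1.40 ± 0.30) and the RNA-binding Igf2bp3 (1.30 ± 0.19) among them besides Akr1c18 and Ccnd1. MHC class II genes had a median of 1.66, with 0 of 7 called and 5 adjusted over the list alone (camera adjusted p = 6.99e-05). H2-Ab1 and Cd74 were at 2.37 ± 0.30 and 2.24 ± 0.25 without the arrays in doubt. Male-biased genes had a median of -0.51, with 2 of 15 lower, Cyp7b1 and Ugt2b38 (-0.72 ± 0.15), and 7 adjusted over the list alone (camera adjusted p = 4.52e-05). With an estimated correlation each of these 4 lists had an adjusted p = 0.344. Of 19 death receptor genes 2 rose and, adjusted over the list alone, 5 rose and 1 fell (camera adjusted p = 0.00151, adjusted p = 0.344 with an estimated correlation). They were Tnfrsf12a (1.52 ± 0.32) and the cytokine gene Tnf (0.97 ± 0.21), and Tnf was the 1 gene called of 25 NF-kB targets, with 2 adjusted over the list alone (camera adjusted p = 0.231). Cyp7b1 fell and the bile acid carrier Slc10a2 (1.14 ± 0.21) and the phospholipid exporter Abcb4 (0.50 ± 0.11) rose among 24 bile acid genes. There 2 were higher and 6 lower adjusted over the list alone (camera adjusted p = 0.0213, adjusted p = 0.596 with an estimated correlation).

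The count of genes called in NEMO knockout liver rested on single arrays. It was 28, 43 and 1409 without liver control 1, 2 and the array labelled liver control 3, and 116, 140 and 23 without NEMO knockout 1, 2 and 3. A fit on the 2 groups alone called 26 genes, 24 higher and 2 lower. Of the 41 called genes named for this comparison, Akr1c18, Gldn and Ccnd1 among them, 8 kept the call without any 1 array. Without control 1 and 2 and without NEMO knockout 1, 2 and 3, 31, 28, 13, 12 and 33 of them lost it, at adjusted p-values of up to 0.171, 0.158, 0.128, 0.0852 and 0.208. Without the 4 arrays in doubt the count was 2265, 1596 higher and 669 lower, and all 251 genes were among them. Then the cell cycle list had 24 of 25 genes higher (25 adjusted over the list alone), the matrix list 25 of 27, and the macrophage list 18 of 21 (19 adjusted over the list alone). Col1a1, a fibrillar collagen, rose by 2.89 ± 0.21, Mki67 by 3.23 ± 0.36, Ly6d by 5.18 ± 0.55 and the elastase Mmp12 by 4.79 ± 0.62.

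**Figure D2:**
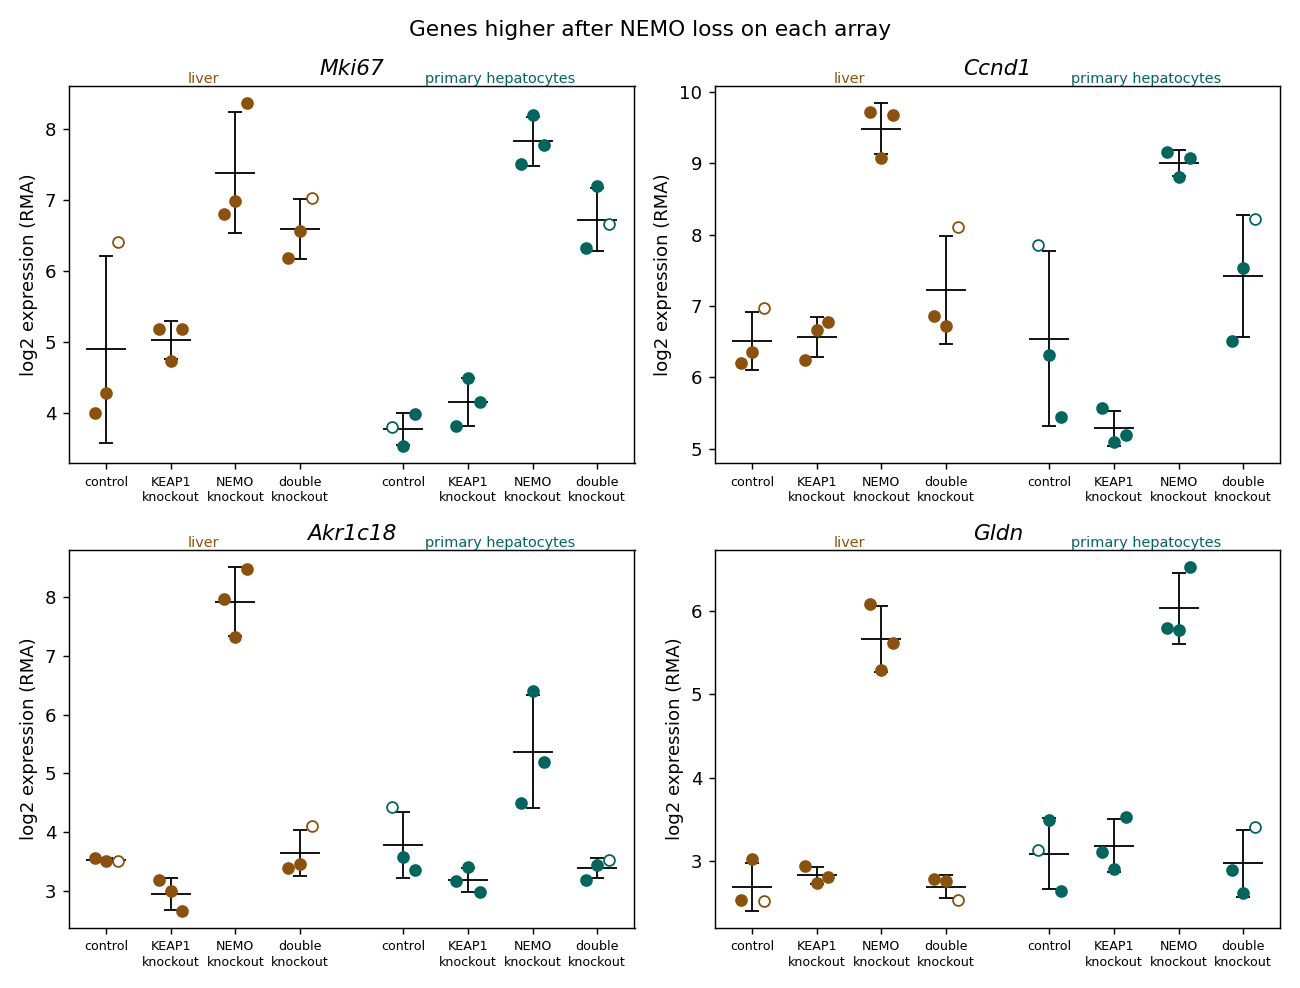
Expression of Mki67, Ccnd1, Akr1c18 and Gldn (log2 RMA values, vertical axes) on each array of the 8 groups (horizontal axes). Points are arrays, open points the 4 arrays in doubt, and bars the mean ± SD of the 3 arrays of a group. In liver Gldn lies between 5.29 and 6.08 on the NEMO knockout arrays and between 2.52 and 3.02 on the other 9.

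KEAP1 loss in liver was compared with control to see what NRF2 release alone changes. With all arrays 0 genes were called by limma, and 1447 had an unadjusted p under 0.05, where 941 would by chance. Nqo1 was at 2.46 ± 0.81 and Cbr3, a carbonyl reductase, at 4.38 ± 1.29 (n = 3 per group, adjusted p = 0.617 for both). The NRF2 target list still stood apart, with 37 of 38 genes above 0, a median of 0.74 and 21 higher adjusted over the list alone (camera adjusted p = 2.37e-20, adjusted p = 0.517 with an estimated correlation). Without the array labelled liver control 3 alone 497 genes were called, and without KEAP1 knockout 3 the count was 1.

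With the 4 arrays in doubt left out, KEAP1 knockout livers had 699 genes higher and 291 lower than the 2 remaining controls. Cbr3 rose by 6.61 ± 0.16, the glutathione peroxidase Gpx2 by 6.23 ± 0.20, Slc7a11 by 5.76 ± 0.21 and the efflux pump Abcc4 by 4.94 ± 0.27 (adjusted p from 8.49e-10 to 9.92e-07). Osbpl3 (4.21 ± 0.26), Nqo1 (3.83 ± 0.19), the protease inhibitor Serpinb1a (3.73 ± 0.35), Anxa13 (3.67 ± 0.18) and the glutamate carrier Slc1a1 (3.62 ± 0.19) rose as well. Of 38 NRF2 targets 30 rose and 36 did adjusted over the list alone (adjusted p = 0.0272 with an estimated correlation). Of 14 glutathione genes 8 rose and 1 fell, with the same counts over the list alone (adjusted p = 0.0442 with an estimated correlation). Among them Gclc, of the rate-limiting enzyme of glutathione synthesis, was at 1.17 ± 0.11 and Gsr at 1.00 ± 0.10. Among genes that fell were Hsd3b5, a male-predominant steroid dehydrogenase (-4.09 ± 0.72), Adgrf1 (-3.49 ± 0.31), the aminotransferase Kyat3 (-3.33 ± 0.24), and Igfbp2 (-2.95 ± 0.27). The transcription factor Onecut1 (-2.89 ± 0.38), Socs2, a brake on growth hormone signalling (-2.53 ± 0.42), and Fabp5 (-2.25 ± 0.22) fell as well. Beside them 8 of 18 stellate cell genes were higher (10 adjusted over the list alone, adjusted p = 0.304 with an estimated correlation). So were 10 of 27 matrix genes (18 higher and 1 lower over the list alone, adjusted p = 0.263) and 5 of 16 endothelial genes (12 over the list alone, adjusted p = 0.263). Col1a1 rose by 1.33 ± 0.21 and the endothelial receptor Lyve1 by 1.43 ± 0.27.

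The double knockout liver was set against the NEMO knockout liver to see what NRF2 release changes where NEMO is absent. Among the 38 NRF2 targets 8 were higher (adjusted p = 0.417 with an estimated correlation), while Akr1c18, Gldn and Ccnd1 were lower. The fit held all 12 liver arrays, so the controls, the array labelled liver control 3 among them, entered the estimate of the spread. Slc7a11 rose by 7.01 ± 1.31, Cbr3 by 6.28 ± 1.29, Slc1a1 by 4.20 ± 0.78 and the urate carrier Slc22a12 by 3.23 ± 0.67 (n = 3 per group, adjusted p from 0.0284 to 0.0436). Il1f9, an interleukin of epithelia (2.89 ± 0.43), the guanylate cyclase Gucy2c (2.81 ± 0.58), Coro6 (2.70 ± 0.47), Meig1 (2.57 ± 0.41), Plekhb1 (2.57 ± 0.33) and Styk1 (2.18 ± 0.46) rose as well. Akr1c18 fell by 4.28 ± 0.27 (adjusted p = 3.38e-05), Gldn by 2.97 ± 0.20 (adjusted p = 3.58e-05), Prelid2 by 2.50 ± 0.41 and Ccnd1 by 2.25 ± 0.33. The apolipoprotein Apoa4 (-3.05 ± 0.55), Igfbp2 (-2.99 ± 0.56), the vasopressin receptor Avpr1a (-2.39 ± 0.44), the melatonin receptor Mtnr1a (-2.35 ± 0.24) and Gdf10 (-2.04 ± 0.34) fell too. In all, 78 genes were higher and 119 lower. A fit on the 2 groups alone called 333 genes, 186 higher and 147 lower, with 156 of the 197 among them.

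Of 38 NRF2 targets in this comparison 8 rose, and 24 rose and 1 fell adjusted over the list alone, with a median of 0.91 (camera adjusted p = 1.57e-20, adjusted p = 0.417 with an estimated correlation). They include Cyp2a5 (2.14 ± 0.41) and Gclc (1.19 ± 0.24). Of 14 glutathione genes Slc7a11, Gclc and Gsr (1.16 ± 0.24) rose, with 5 higher and 1 lower over the list alone (camera adjusted p = 0.00699, adjusted p = 0.503 with an estimated correlation). Of 22 PPARalpha and fatty acid oxidation genes 5 fell and 6 did over the list alone, with a median of -0.13 (camera adjusted p = 0.000681, adjusted p = 0.417 with an estimated correlation). They were led by Cyp4a14, a fatty acid hydroxylase (-3.42 ± 0.54), Cyp4a31 (-1.61 ± 0.31) and the thioesterases Acot2 (-1.29 ± 0.21) and Acot1 (-0.73 ± 0.15). Of 20 lipogenesis genes the elongases Elovl6 (-1.02 ± 0.15) and Elovl5 (-0.90 ± 0.19) fell, with 1 higher and 6 lower over the list alone (camera adjusted p = 0.000365, adjusted p = 0.417 with an estimated correlation). Ccnd1 was the 1 gene called of 25 of the cell cycle, where 4 fell over the list alone (median -0.57, camera adjusted p = 3.47e-06, adjusted p = 0.708 with an estimated correlation). Eda2r (-1.34 ± 0.20) was the 1 of 15 p53 targets, also 1 over the list alone (camera adjusted p = 0.000677, adjusted p = 0.417 with an estimated correlation). Of 21 macrophage and 27 matrix genes 0 were called by limma, with 0 higher or lower over the list alone in the first and 2 lower in the second.

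The count in this comparison was 81, 68 and 23 without NEMO knockout 1, 2 and 3, and 16 and 46 without double knockout 1 and 2. Of the 31 called genes named for this comparison 5 kept the call without any 1 array, Akr1c18 and Gldn among them. Without NEMO knockout 1, 2 and 3, 18, 17 and 24 lost it, at adjusted p-values of up to 0.121, 0.17 and 0.175. Without double knockout 1, 2 and 3, 26, 22 and 12 did, at up to 0.173, 0.152 and 0.107. The count was 651 without the 4 arrays in doubt, 361 higher and 290 lower, including all 197. Then 26 of 38 NRF2 targets rose, 30 over the list alone (adjusted p = 0.0323 with an estimated correlation), Gpx2 by 5.56 ± 0.20 and Nqo1 by 3.52 ± 0.19, while Slc7a11 was at 6.85 ± 0.21.

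Against control, the double knockout liver had 1 gene called, Angptl8 (-1.53 ± 0.17, n = 3 per group, adjusted p = 0.0147), and 3901 at an unadjusted p under 0.05. With the replicate number as a block 520 genes were higher and 279 lower, Angptl8 among them (adjusted p = 0.0102), while a fit on the 2 groups alone called 0 genes. That the number pairs these arrays is not established. Both arrays numbered 3 are in doubt, and the block can take up what sets them apart. NRF2 targets had a median of 0.83, with 26 of 38 higher and 1 lower adjusted over the list alone (camera adjusted p = 7.91e-13, adjusted p = 0.369 with an estimated correlation). The matrix list had a median of 1.17 with 24 of 27 higher over the list alone (camera adjusted p = 7.91e-13). The cell cycle list had a median of 0.91 with 16 of 25 (camera adjusted p = 6.04e-11), and both had an adjusted p = 0.369 with an estimated correlation. The count was 0 without liver control 1 or 2 or double knockout 1 or 2, where Angptl8 had an adjusted p of 0.16, 0.116, 0.13 and 0.148, 2 without double knockout 3, and 2207 without the array labelled liver control 3. Without the 4 arrays in doubt (n = 2 per group) 1198 genes were higher and 534 lower, with Slc7a11 at 7.22 ± 0.23, Cbr3 at 6.84 ± 0.18, Ly6d at 4.55 ± 0.60, Hsd3b5 at -6.27 ± 0.79 and the adipokine Serpina12 at -3.59 ± 0.24. Against the KEAP1 knockout liver 0 genes were called by limma in the double knockout, with 1429 at an unadjusted p under 0.05. That count was 2 without KEAP1 knockout 3, 1 without double knockout 3 and 2 in a fit on the 2 groups alone. Without the 4 arrays in doubt it was 10, with Mpped1 (1.66 ± 0.16), the scavenger receptor Marco (1.48 ± 0.22) and Slc7a11 (1.46 ± 0.21) higher and Serpina12 (-2.31 ± 0.22) and the pyruvate kinase Pklr (-1.26 ± 0.18) lower.

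NEMO knockout hepatocyte cultures had 22 of 25 cell cycle genes and 16 of 18 stellate cell markers higher than control cultures (adjusted p = 0.0137 and 0.00791 with an estimated correlation). Higher as well were 15 of 21 macrophage and 15 of 16 endothelial markers (adjusted p = 0.0842 and 0.052 with an estimated correlation). The deletion was in hepatocytes, so the rise of markers of other cells may come from a different share of such cells, as weighed below. D17H6S56E-5 rose by 4.72 ± 0.39 (n = 3 per group, adjusted p = 1.68e-05), Mki67, a marker of dividing cells, by 4.04 ± 0.24 (adjusted p = 4.82e-06), Mmp12 by 3.98 ± 0.40, Ccna2 by 3.94 ± 0.31 and Hmmr, a spindle protein, by 3.92 ± 0.30. Ly6d (3.61 ± 0.23), Knstrn (3.61 ± 0.36), Ect2, an exchange factor of cell division (3.40 ± 0.30), Ccnb2 (3.38 ± 0.32) and Prc1 (3.31 ± 0.24) rose as well, with adjusted p-values of these 10 genes of at most 6.63e-05. The genes that fell most were Pcp4l1 (-2.53 ± 0.50), Rgs16 (-2.23 ± 0.55), the clock repressor Ciart (-2.02 ± 0.38), the acute phase gene Saa3 (-1.99 ± 0.33), Ppp1r3g, which directs a phosphatase to glycogen (-1.95 ± 0.29), and the chemokine Cxcl9 (-1.94 ± 0.26). They were followed by Serpina12 (-1.87 ± 0.37), Bhlhe41 (-1.81 ± 0.40), the interferon-induced Ifit1 (-1.73 ± 0.30) and the lipid carrier Mfsd2a (-1.66 ± 0.39). In all, 867 genes were higher and 385 lower. With array medians made equal the 1417 calls divided differently, 56.1% higher against 69.2%, and without NEMO knockout 1 the count was 807. Leaving out the 4 arrays in doubt gave 779 higher and 272 lower.

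Of 25 cell cycle genes in NEMO knockout hepatocytes 22 rose, also 22 over the list alone, with a median of 2.25 (camera adjusted p = 4.94e-34, adjusted p = 0.0137 with an estimated correlation). Beside them 16 of 18 stellate cell markers rose, 17 over the list alone (median 1.46, adjusted p = 0.00791 with an estimated correlation). Dcn (3.18 ± 0.25), Bgn (2.86 ± 0.19), the retinol-esterifying Lrat (2.50 ± 0.25) and Reln (2.13 ± 0.19) were among them. Of 21 macrophage markers 15 rose, 17 over the list alone (median 1.74, camera adjusted p = 4.28e-19, adjusted p = 0.0842 with an estimated correlation). They were led by the complement gene C1qb (2.31 ± 0.30), Cd68 (2.31 ± 0.25), Marco (2.25 ± 0.20) and Vsig4 (2.21 ± 0.28). Of 16 endothelial markers 15 rose, also over the list alone (median 1.57, camera adjusted p = 1.31e-23, adjusted p = 0.052 with an estimated correlation), such as Eng (1.95 ± 0.20) and Clec4g (1.92 ± 0.23). The endothelial Pecam1 lay between 4.74 and 5.29 in control cultures and between 5.79 and 6.85 in all knockout cultures. MHC class II genes rose with the macrophage markers, 5 of 7 and 6 over the list alone (adjusted p = 0.0272 with an estimated correlation), with H2-Ab1 at 2.17 ± 0.19 and Cd74 at 1.99 ± 0.24. Matrix genes rose with the stellate markers, 16 of 27 and 18 over the list alone (adjusted p = 0.0137 with an estimated correlation). Anxa2 was at 2.62 ± 0.27, the intermediate filament Vim at 2.19 ± 0.20 and the protease inhibitor Timp2 at 1.68 ± 0.17. Of 21 dedifferentiation genes, which share Anxa2 and Vim with that list, 12 rose and 13 did over the list alone (adjusted p = 0.0499 with an estimated correlation).

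Other lists were tested in the NEMO knockout cultures. Of 22 hepatocyte identity genes 2 fell, the transcription factor Cebpa (-0.75 ± 0.12) and the tryptophan-degrading Tdo2 (-0.41 ± 0.10), with 4 over the list alone and a median of -0.06 (camera adjusted p = 0.0219, adjusted p = 0.203 with an estimated correlation). Of 18 cholesterol synthesis genes 5 fell and 9 did over the list alone, such as Stard4 (-0.70 ± 0.14) and Msmo1 (-0.65 ± 0.15) (camera adjusted p = 5.04e-06, adjusted p = 0.349 with an estimated correlation). Of 15 clock genes 5 fell, with 3 higher and 8 lower over the list alone (camera adjusted p = 0.0179, adjusted p = 0.0827 with an estimated correlation), among them Tef (-1.55 ± 0.34) and Per2 (-1.19 ± 0.29) besides Ciart and Bhlhe41. Times of day are not given in the sources used here. Of 24 interferon genes 3 fell and 1 rose, with 3 higher and 8 lower over the list alone (camera adjusted p = 0.0118, adjusted p = 0.357 with an estimated correlation). Cxcl9, Ifit1 and Isg15 (-0.88 ± 0.19) fell and Oasl2 (0.79 ± 0.18) rose. Of 15 p53 targets 3 rose and 5 did over the list alone (adjusted p = 0.0496 with an estimated correlation, and 0.0646 without the arrays in doubt), the mitotic Gtse1 (1.42 ± 0.20), Eda2r (1.13 ± 0.21) and the death receptor Tnfrsf10b (0.95 ± 0.19). Of 38 NRF2 targets 2 rose and 2 fell, with 3 and 4 over the list alone (median -0.07, camera adjusted p = 0.916). Of the 49 called genes named for this comparison 38 kept the call without any 1 array. Without control 1, 2 and 3, 7, 7 and 4 lost it, at adjusted p-values of up to 0.17, 0.0904 and 0.093. Without NEMO knockout 1, 2 and 3, 8, 9 and 5 did, at up to 0.135, 0.181 and 0.095, Rgs16, Bhlhe41 and Mfsd2a among them.

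KEAP1 knockout hepatocyte cultures had 14 of 38 NRF2 targets and 15 of 16 endothelial markers higher and 6 of 18 cholesterol synthesis genes lower than control cultures (adjusted p = 0.0945, 0.0945 and 0.103 with an estimated correlation). The deletion was in hepatocytes, so the endothelial rise may come from a different share of other cells in the cultures, as weighed below. Cbr3 rose by 5.22 ± 0.24 (n = 3 per group, adjusted p = 2.54e-07), Anxa13 by 4.35 ± 0.21, Gpx2 by 3.74 ± 0.45, the sterol-binding Osbpl3 by 3.59 ± 0.21 and Slc22a12 by 3.10 ± 0.28. Abcc4 (3.10 ± 0.33), Serpinb1a (3.08 ± 0.56), Slc1a1 (3.06 ± 0.21), Nrxn2 (2.58 ± 0.15) and Tinag (2.51 ± 0.23) rose as well, with adjusted p-values of at most 0.0125. The genes that fell were led by Nxpe2 (-3.01 ± 0.20, adjusted p = 4.36e-06), Kyat3 (-2.40 ± 0.35), Acnat2 (-2.05 ± 0.48), Avpr1a (-1.95 ± 0.21), Igfbp2 (-1.89 ± 0.39), Chic1 (-1.81 ± 0.31), and the sulfotransferase Sult1c2 (-1.66 ± 0.39). Golm2 (-1.59 ± 0.26), the organic anion carrier Slc22a7 (-1.57 ± 0.14) and the transcription factor Klf10 (-1.46 ± 0.31) fell too. Of the 36 called genes named for this comparison 24 kept the call without any 1 array. Without control 1, 2 and 3, 8, 9 and 1 lost it, at adjusted p-values of up to 0.126, 0.101 and 0.0538. Without KEAP1 knockout 1, 2 and 3, 11, 10 and 10 did, at up to 0.193, 0.155 and 0.115, Serpinb1a, Acnat2, Igfbp2, Sult1c2 and Klf10 among them. In all, 272 genes were higher and 80 lower. The count was 155 in a fit on the 2 groups alone, 120 higher and 35 lower. It was 123, 142 and 216 without KEAP1 knockout 1, 2 and 3, and 342 without the 4 arrays in doubt, 253 higher and 89 lower.

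Of 38 NRF2 targets in KEAP1 knockout hepatocytes 14 rose and 28 did over the list alone, with a median of 0.66 (camera adjusted p = 4.8e-30, adjusted p = 0.0945 with an estimated correlation), Slc7a11 (2.49 ± 0.37) among them. Of 14 glutathione genes 4 rose, and 6 rose and 1 fell over the list alone (camera adjusted p = 2.3e-05, adjusted p = 0.0945 with an estimated correlation). Gclc was at 0.91 ± 0.12, Gpx4 at 0.54 ± 0.09 and Gsr at 0.54 ± 0.08. Pgd, of the pentose phosphate pathway, was the 1 of 9 genes of that list called, at 0.99 ± 0.21, with 4 over the list alone (camera adjusted p = 0.0471, adjusted p = 0.443 with an estimated correlation). Beside the NRF2 targets 15 of 16 endothelial markers rose, also over the list alone, with a median of 1.34 (camera adjusted p = 3.51e-26, adjusted p = 0.0945 with an estimated correlation). Lyve1 (1.93 ± 0.24), Oit3 (1.77 ± 0.20), Dnase1l3 (1.64 ± 0.20) and Gpr182 (1.60 ± 0.25) rose most. Of 21 macrophage markers 3 rose and 12 did over the list alone (median 0.85, camera adjusted p = 3.2e-09, adjusted p = 0.361 with an estimated correlation). Of 18 stellate markers 4 rose and 8 did over the list alone (median 0.33, camera adjusted p = 1.49e-07, adjusted p = 0.103 with an estimated correlation). Of 18 cholesterol synthesis genes 6 fell and all 18 did over the list alone, with a median of -0.68 (camera adjusted p = 3.57e-19, adjusted p = 0.103 with an estimated correlation). They include Fdps (-0.87 ± 0.18), Idi1 (-0.80 ± 0.10), Msmo1 (-0.72 ± 0.15) and Srebf2, the transcription factor of the pathway (-0.66 ± 0.13). Of 20 lipogenesis genes Elovl5 (-0.85 ± 0.12), Pklr (-0.74 ± 0.15) and Acaca, the acetyl-CoA carboxylase (-0.60 ± 0.13), fell, and 10 did over the list alone (camera adjusted p = 1.19e-08, adjusted p = 0.103 with an estimated correlation). Of 25 cell cycle genes 0 were called by limma or over the list alone (median 0.24, camera adjusted p = 0.0984).

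In hepatocytes without NEMO, further loss of KEAP1 raised 25 of 38 NRF2 targets, and raised 6 of 14 glutathione genes and lowered 1 (adjusted p = 0.047 and 0.0276 with an estimated correlation). Without the 4 arrays in doubt both had an adjusted p = 0.0737 with an estimated correlation. Cbr3 rose by 6.52 ± 0.24 (n = 3 per group, adjusted p = 1.51e-08), Gpx2 by 6.06 ± 0.45, Slc7a11 by 6.03 ± 0.37, Abcc4 by 5.44 ± 0.33 and Anxa13 by 4.37 ± 0.21. Nqo1 (3.91 ± 0.51), the elongase Elovl7 (3.88 ± 0.41), the acute phase gene Orm3 (3.67 ± 0.65), Slc1a1 (3.66 ± 0.21) and Gucy2c (3.62 ± 0.26) rose as well. The genes that fell were led by Slco1a1, a male-predominant organic anion carrier (-5.69 ± 0.79, adjusted p = 0.0015), Hsd3b5 (-5.32 ± 1.32, adjusted p = 0.0466), Nxpe2 (-3.36 ± 0.20), Avpr1a (-3.19 ± 0.21) and Gldn (-3.05 ± 0.28). Adgrf1 (-2.56 ± 0.43), Susd4 (-2.54 ± 0.56), Med12l (-2.20 ± 0.25), Sdr9c7 (-2.08 ± 0.24) and Igfbp2 (-2.05 ± 0.39) fell as well. Of the 48 called genes named for this comparison 29 kept the call without any 1 array. Without NEMO knockout 1, 2 and 3, 11, 16 and 11 lost it, at adjusted p-values of up to 0.152, 0.148 and 0.115. Without double knockout 1, 2 and 3, 11, 14 and 7 did, at up to 0.137, 0.165 and 0.123, Hsd3b5, Susd4 and Igfbp2 among them. In all, 406 genes were higher and 218 lower. The count was 320, 293 and 389 without NEMO knockout 1, 2 and 3, 378 and 347 without double knockout 1 and 2, and 716 without the 4 arrays in doubt, 449 higher and 267 lower.

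Of 38 NRF2 targets in this comparison 25 rose and 31 did over the list alone, with a median of 0.84 (adjusted p = 0.047 with an estimated correlation). Of 14 glutathione genes 6 rose and 1 fell, with 10 and 1 over the list alone (adjusted p = 0.0276 with an estimated correlation), among them Gpx3 (1.36 ± 0.24), Gclc (1.07 ± 0.12) and Gsr (0.89 ± 0.08). Of 9 pentose phosphate and NADPH genes 4 rose, also over the list alone, Pgd (1.75 ± 0.21), Tkt (0.79 ± 0.12), Pgls (0.62 ± 0.14) and Taldo1 (0.52 ± 0.12) (camera adjusted p = 5.67e-05, adjusted p = 0.155 with an estimated correlation). Of 16 metallothionein and iron genes 2 rose and 6 did over the list alone, Hfe (0.68 ± 0.12) and the ferritin gene Ftl1 (0.45 ± 0.09) (adjusted p = 0.047 with an estimated correlation, and 0.0737 without the arrays in doubt). Of 22 acute phase genes 4 rose, also over the list alone, Orm3, the siderophore-binding Lcn2 (3.00 ± 0.51), Orm2 (1.85 ± 0.38) and Lbp (0.77 ± 0.17) (camera adjusted p = 5.67e-05, adjusted p = 0.353 with an estimated correlation). Of 25 cell cycle genes 7 fell and 16 did over the list alone, with a median of -0.78 (camera adjusted p = 3.54e-10, adjusted p = 0.21 with an estimated correlation). Cenpf (-1.16 ± 0.24), Mki67 (-1.10 ± 0.24) and Prc1 (-1.03 ± 0.24) were among them. Macrophage markers stood higher in the same cultures, 3 of 21 and 5 over the list alone (camera adjusted p = 9.78e-06, adjusted p = 0.439 with an estimated correlation), Cd14 (1.43 ± 0.33), Marco (1.28 ± 0.20) and the integrin Itgam (1.08 ± 0.20). A different share of macrophages in these cultures was not tested. Of 15 male-biased genes Slco1a1, Hsd3b5 and Mup3 (-1.99 ± 0.41) fell and 4 did over the list alone (median -1.50, camera adjusted p = 5.67e-05, adjusted p = 0.475 with an estimated correlation). Without the arrays of high Xist, hepatocyte control 1 and double knockout 3, that median was -0.55, with Slco1a1 at -5.25 ± 0.32, Hsd3b5 at -4.77 ± 0.27 and Mup3 at -1.44 ± 0.20, all 3 called (adjusted p = 2e-06, 1.48e-06 and 0.00186).

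Against control, double knockout hepatocytes had 1267 genes higher and 563 lower. With medians made equal 58.4% of 1894 calls were higher against 69.2%. The count was 1150 in a fit on the 2 groups alone (900 higher and 250 lower) and 1042 without double knockout 2. Without the 4 arrays in doubt (n = 2 per group) it was 1738, 1212 higher and 526 lower. Slc7a11 rose by 5.93 ± 0.37 (n = 3 per group, adjusted p = 1.19e-06), Cbr3 by 5.86 ± 0.24, Ly6d by 5.36 ± 0.23, Gpx2 by 5.26 ± 0.45 and Anxa13 by 4.78 ± 0.21. Slco1a1 fell by 4.88 ± 0.79, Nxpe2 by 3.46 ± 0.20, Adgrf1 by 3.25 ± 0.43, Serpina12 by 3.03 ± 0.37 and Avpr1a by 2.55 ± 0.21. Of 38 NRF2 targets 29 rose and 31 did over the list alone (adjusted p = 0.0428 with an estimated correlation). Of 21 macrophage markers 19 rose and 21 did over the list alone, and of 16 endothelial markers 15 rose and 16 did over the list alone (adjusted p = 0.0488 for both with an estimated correlation). Without the 4 arrays in doubt these 3 lists had adjusted p = 0.0657, 0.0657 and 0.0772 with an estimated correlation. A different share of other cells in the cultures may account for the macrophage and endothelial rise, which was not tested in this comparison. Lipogenesis genes fell beside these lists, 8 of 20 with 1 higher, and 11 and 1 over the list alone (camera adjusted p = 2.84e-07, adjusted p = 0.0798 with an estimated correlation). Pklr fell by 1.96 ± 0.15, the fatty acid synthase gene Fasn by 1.23 ± 0.35 and its regulator Srebf1 by 1.22 ± 0.27. Of 13 gluconeogenesis and glycogen genes 6 fell, also over the list alone (camera adjusted p = 0.00128, adjusted p = 0.0798 with an estimated correlation). Ppp1r3g was at -1.96 ± 0.29, the glycogen synthase Gys2 at -0.66 ± 0.17 and the glycogen phosphorylase Pygl at -0.52 ± 0.07. Of the 17 called genes named for this comparison 14 kept the call without any 1 array. Without control 1 and 2, 1 and 3 lost it (Fasn at an adjusted p of 0.126 and 0.14), and without double knockout 1, 2 and 3, 1, 3 and 1 (Gys2 at 0.0933 and 0.116, Fasn at 0.125).

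In hepatocyte cultures without KEAP1, further loss of NEMO raised 407 genes and lowered 111. The rise of markers of other cells below may come from a different share of such cells, which was not tested in this comparison. The largest rises were Mmp12 (3.89 ± 0.40, n = 3 per group, adjusted p = 0.000547), Slc7a11 (3.45 ± 0.37), Sprr1a (3.39 ± 0.30), Elovl7 (3.35 ± 0.41) and Lcn2 (3.23 ± 0.51). The largest falls were Hsd3b5 (-5.80 ± 1.32), Slco1a1 (-5.09 ± 0.79), Serpina12 (-2.64 ± 0.37), Adgrf1 (-2.07 ± 0.43) and Onecut1 (-2.01 ± 0.49). Of the 16 called genes named for this comparison 12 kept the call without any 1 array. Without KEAP1 knockout 1, 2 and 3, 4, 3 and 3 lost it, at adjusted p-values of up to 0.149, 0.0921 and 0.173. Without double knockout 1, 2 and 3, 1, 3 and 3 did, at up to 0.074, 0.189 and 0.121, Hsd3b5, Adgrf1 and Onecut1 among them. Of 25 cell cycle genes 16 rose and 22 did over the list alone, with a median of 1.27 (adjusted p = 0.0335 with an estimated correlation), Mki67 by 2.56 ± 0.24. Of 18 stellate markers 10 rose and 13 did over the list alone (adjusted p = 0.0335 with an estimated correlation). Of 21 macrophage markers 10 rose and 20 did over the list alone (camera adjusted p = 2.2e-22, adjusted p = 0.0701 with an estimated correlation), with Marco at 2.89 ± 0.20 and Gpnmb at 2.27 ± 0.28. Of 19 oncofetal genes 7 rose, also over the list alone (adjusted p = 0.0361 with an estimated correlation), Ly6d at 3.09 ± 0.23 and Spink1 at 1.70 ± 0.34 among them. The cell cycle, stellate and oncofetal lists had an adjusted p = 0.0531 with an estimated correlation without the 4 arrays in doubt. The count was 239, 337 and 196 without KEAP1 knockout 1, 2 and 3, 157 without double knockout 2, and 711 without the 4 arrays in doubt, 533 higher and 178 lower.

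Of 16 urea cycle and amino acid genes 3 fell in NEMO knockout hepatocytes and 6 did over the list alone (camera adjusted p = 0.000756, adjusted p = 0.349 with an estimated correlation). The histidine-degrading Hal (-0.61 ± 0.17) and the proline dehydrogenase Prodh (-0.41 ± 0.11) were among them. In double against NEMO knockout hepatocytes the P450 enzymes Cyp2a5 (1.83 ± 0.25), Cyp1a2 (0.71 ± 0.10) and Cyp3a13 (0.53 ± 0.10) rose and Cyp3a11 (-0.42 ± 0.09) fell among 23, with 4 higher and 2 lower over the list alone (camera adjusted p = 0.097). The proteasome subunit Psmb5 rose by 0.62 ± 0.10, the 1 gene called of 30 and also 1 over the list alone (camera adjusted p = 0.035, adjusted p = 0.353 with an estimated correlation). Of 16 autophagy and lysosome genes Map1lc3b (0.45 ± 0.11) and the protease Ctsd (0.43 ± 0.09) rose, and 3 did over the list alone (camera adjusted p = 0.00388, adjusted p = 0.337 with an estimated correlation). In double against NEMO knockout liver the chaperone Dnajb9 (1.00 ± 0.15) was the 1 gene called of 18 of the unfolded protein response, with 3 over the list alone (camera adjusted p = 0.0124, adjusted p = 0.417 with an estimated correlation). Neutrophil markers had a median of 0.49 there, with 0 of 11 called by limma (camera adjusted p = 0.00108, adjusted p = 0.417 with an estimated correlation). In NEMO knockout liver 0 of 11 cholangiocyte markers were called by limma and 2 were higher over the list alone (median 0.41, camera adjusted p = 0.0805). Of T and natural killer cell markers and of B cell markers, 16 and 10 genes, 0 were called by limma or over the list alone in NEMO knockout liver (camera adjusted p = 0.125 and 0.174) or hepatocytes (camera adjusted p = 0.939 for both). Only 3 erythroid markers were measured, too few for the test, and their median was -0.21 in NEMO knockout liver.

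Whether the knockouts add up was tested by their interaction, where a negative value means that the double knockout lies below the sum of the single effects. In liver 2 genes were called, Akr1c18 (-3.70 ± 0.38, n = 3 per group, adjusted p = 0.00444) and Gldn (-3.11 ± 0.28, adjusted p = 0.00218). Gldn lay near the background on all liver arrays but those of the NEMO knockout. A fall of Gldn with KEAP1 loss alone could therefore not be seen, and its interaction is uncertain. The count was 14 without the array labelled liver control 3, 5 without NEMO knockout 2, 8 without double knockout 3 and 65 without the 4 arrays in doubt, 12 higher and 53 lower. There Ccnd1 was at -2.98 ± 0.27 and Prelid2 at -3.41 ± 0.56. In hepatocytes 8 genes were called, Slc7a11 (3.54 ± 0.53), the zinc carrier Slc39a2 (3.37 ± 0.51), Klhdc2 (1.08 ± 0.15) and the insulin-degrading enzyme Ide (0.67 ± 0.10) above the sum. Below it lay Gldn (-3.14 ± 0.39), Bgn (-2.12 ± 0.26), the endothelial Plvap (-1.77 ± 0.25) and Tmem47 (-1.58 ± 0.21), with adjusted p from 0.0208 to 0.038. The count was 16, 72 and 27 without control 1, 2 and 3, and 0, 3 and 4 without KEAP1 knockout 1, 2 and 3. It was 0, 0 and 4 without NEMO knockout 1, 2 and 3, 0 without double knockout 2 and 22 without the 4 arrays in doubt. Each of the 8 genes lost the call without KEAP1 knockout 1, NEMO knockout 1 or 2 or double knockout 2 (adjusted p up to 0.136, 0.116, 0.112 and 0.0793). Without KEAP1 knockout 2 and 3, NEMO knockout 3 and double knockout 1 and 3, 6, 5, 5, 3 and 1 did (adjusted p up to 0.0785, 0.072, 0.088, 0.0631 and 0.0539). In hepatocytes the cell cycle list had a median interaction of -0.98, with 0 of 25 genes called by limma and 14 lower over the list alone (camera adjusted p = 8.35e-12, adjusted p = 0.134 with an estimated correlation). The endothelial list was at -1.20 with 15 of 16 lower over the list alone (camera adjusted p = 3.98e-17, adjusted p = 0.134 with an estimated correlation). Its median change against control was 1.344, 1.572 and 1.733 in KEAP1, NEMO and double knockout cultures. The deletions were in hepatocytes. For this list, the endothelial Plvap and the stellate marker Bgn, a different share of other cells may account for the interaction, which was not tested. The NRF2 list was at 0.32 with 1 of 38 higher and 7 over the list alone (camera adjusted p = 1.52e-06, adjusted p = 0.336 with an estimated correlation).

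Effects in liver and in hepatocytes were compared by their difference, liver minus hepatocytes. For NEMO loss 13 genes differed, with Prelid2 (3.55 ± 0.65) and Akr1c18 (2.81 ± 0.51) changed more in liver. The stromal and endothelial genes Dcn (-2.16 ± 0.39), Rgs5 (-1.99 ± 0.35), Ecm1 (-1.79 ± 0.30), Plvap (-1.74 ± 0.30) and Calcrl (-1.57 ± 0.27) changed more in culture (n = 3 per group, adjusted p = 0.0374 for these 7). A different share of other cells in the cultures may account for these stromal and endothelial genes, which was not tested for them. Zfp791 was at 1.07 ± 0.20 (adjusted p = 0.0437). The count was 0, 47 and 2 without hepatocyte control 1, 2 and 3, 0, 6 and 0 without hepatocyte NEMO knockout 1, 2 and 3. It was 40, 0 and 25 without liver control 1, 2 and the array labelled liver control 3, and 1, 7 and 0 without liver NEMO knockout 1, 2 and 3. The 8 named genes all lost the call without hepatocyte control 1 or 3, hepatocyte NEMO knockout 1 or 3, liver control 2 or liver NEMO knockout 1 or 3 (adjusted p up to 0.103, 0.0939, 0.144, 0.1, 0.121, 0.154 and 0.103). Without hepatocyte NEMO knockout 2, liver control 1, the array labelled liver control 3 and liver NEMO knockout 2, 5, 2, 1 and 5 did (adjusted p up to 0.0629, 0.0559, 0.0642 and 0.0879). The count was 12 without the 4 arrays in doubt, 10 higher and 2 lower, and 1 of the 13 genes was among them, Prelid2 at 4.009 ± 0.605. The other 7 named genes lost the call there (adjusted p from 0.07 to 0.0909), while Dpt (2.355 ± 0.418) and Col1a1 (1.818 ± 0.283) were above 0 and called. The endothelial list differed by a median of -1.41, with 0 of 16 called by limma and 15 lower over the list alone (camera adjusted p = 1.37e-23, adjusted p = 0.0877 with an estimated correlation). The cholesterol list differed by 0.60, with 0 of 18 called and 11 higher over the list alone (camera adjusted p = 1.78e-13, adjusted p = 0.23 with an estimated correlation). For KEAP1 loss 0 genes were called by limma, with 1069 at an unadjusted p under 0.05. The endothelial list was at -0.95 with 13 of 16 lower over the list alone (camera adjusted p = 8.78e-17) and the cholesterol list at 0.56 with 9 of 18 higher over the list alone (camera adjusted p = 6.46e-17), each at an adjusted p = 0.151 with an estimated correlation. That count was 5 without hepatocyte control 2, 3 without liver control 1, 2 without the array labelled liver control 3 and 2 without the 4 arrays in doubt. For double against NEMO knockout 0 genes were called by limma, with 879 at an unadjusted p under 0.05. It was 1 without hepatocyte NEMO knockout 2, hepatocyte double knockout 3, liver NEMO knockout 1 or liver double knockout 3, and 3 without the 4 arrays in doubt.

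Control hepatocytes differed from control liver by 243 genes higher and 723 lower. In culture Fos was higher by 4.61 ± 0.44 (n = 3 per group, adjusted p = 1.02e-06), Jun by 3.88 ± 0.27 and Atf3 by 3.60 ± 0.57. Ppp1r3g was at 4.49 ± 0.36 and Rgs16 at 3.70 ± 0.56. Of 15 clock genes 8 rose and 2 fell, with 9 and 3 over the list alone (adjusted p = 0.00965 with an estimated correlation), Ciart by 2.28 ± 0.35 and Bhlhe40 by 1.99 ± 0.22. All 16 endothelial genes were lower, also over the list alone (median -1.69, adjusted p = 0.00965 with an estimated correlation). So were 14 of 18 stellate genes, 17 over the list alone (median -1.87, adjusted p = 0.0236 with an estimated correlation). Dcn fell by 3.24 ± 0.28, Prelp by 3.09 ± 0.31, Col14a1 by 2.99 ± 0.24, Bgn by 2.89 ± 0.31, Sparcl1 by 2.79 ± 0.48 and Eng by 2.06 ± 0.23. Of 21 macrophage markers 12 fell and 15 did over the list alone (camera adjusted p = 1.68e-16, adjusted p = 0.121 with an estimated correlation). With medians made equal 52.1% of the calls were higher against 25.2%, and the count was 638 without hepatocyte control 1 and 300 in a fit on the 2 groups alone (56 higher and 244 lower). Without the 4 arrays in doubt (n = 2 per group) 138 genes were higher and 438 lower.

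The effect of 1 knockout with and without the other was compared over the 18820 genes, between comparisons that share no array. Genes are not independent replicates. For KEAP1 loss Pearson's r was 0.47 in liver and 0.331 in hepatocytes (Spearman's rho 0.284 and 0.222). For NEMO loss it was 0.548 in liver and 0.471 in hepatocytes (Spearman's rho 0.424 and 0.305). Without the 4 arrays in doubt these r were 0.352, 0.462, 0.428 and 0.56 in the order KEAP1 loss in liver and hepatocytes, then NEMO loss in liver and hepatocytes.

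**Figure D3:**
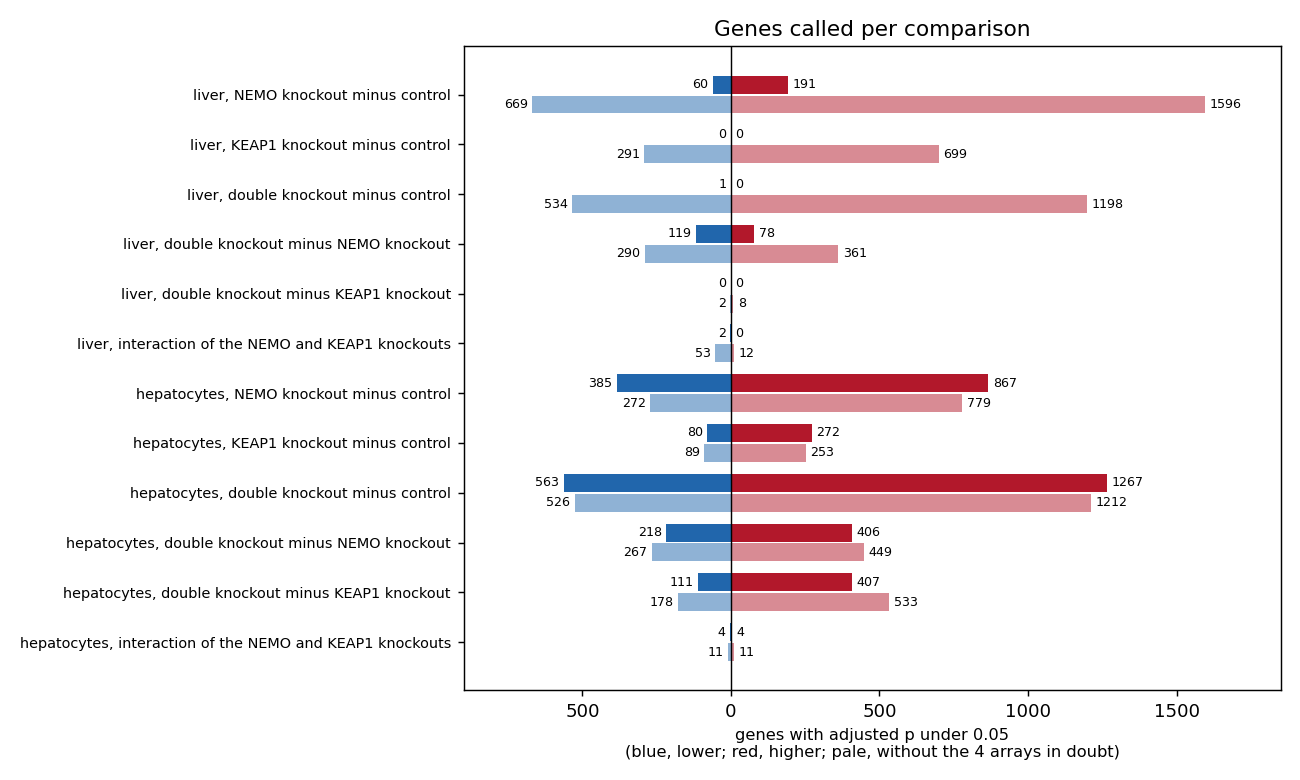
Genes with an adjusted p under 0.05 (horizontal axis, number of genes) in the 12 comparisons within liver or hepatocytes (vertical axis), lower to the left and higher to the right, with all arrays (dark) and without the 4 arrays in doubt (pale). KEAP1 knockout against control in liver has 0 genes with all arrays, and 291 lower and 699 higher without the arrays in doubt.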

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

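The tests of the array labelled liver control 3 by a swap or by Ikbkg, those of the male-biased genes, those of the markers of other cell types, and the choice to leave out 4 arrays were made after the results were seen. The interaction asks whether the double knockout departs from the sum of the single effects. In liver 2 genes did, Gldn (-3.11) and Akr1c18 (-3.70), and that of Gldn is uncertain because it lay near the background. In hepatocytes 8 did, Slc7a11 (3.54), Slc39a2 (3.37), Klhdc2 (1.08), Ide (0.67), Tmem47 (-1.58), Plvap (-1.77), Bgn (-2.12) and Gldn (-3.14). The effect of NEMO loss differed between liver and hepatocytes in 13 genes. They were Prelid2 (3.55), Akr1c18 (2.81), Zfp791 (1.07), Adgrf4 (-0.94), Pde2a (-1.04), Adgrl4 (-1.41), Adgrf5 (-1.47), Ptprb (-1.55), Calcrl (-1.57), Plvap (-1.74), Ecm1 (-1.79), Rgs5 (-1.99) and Dcn (-2.16). Probe sets with no gene symbol or several, 14338 in all, entered no comparison of the report. Called among them were 2 for NEMO loss in liver, 2 for KEAP1 loss in liver and 2 for double against NEMO knockout liver. In hepatocytes they were 51 (48 higher and 3 lower), 1 and 5 in the same order.

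Other splits of the arrays into groups of the same sizes were counted. For comparisons of 3 with 3 arrays there are 10 splits, too few for a share under 0.05, so only counts are given. In liver the real split and the highest other called 251 and 0 genes for NEMO loss, 0 and 45 for KEAP1 loss, 1 and 1 for the double knockout, 197 and 4 for double against NEMO knockout, and 0 and 1 for double against KEAP1 knockout. As many genes as the real split came from 1, 10, 3, 1 and 10 of the 10 splits. In hepatocytes the counts were 1252 and 0, 352 and 1, 1830 and 18, 624 and 1, and 518 and 0 in the same order, and control hepatocytes against control liver gave 966 and 45, each reached by 1 split. For the interaction 4 of 100 splits gave the 8 genes of hepatocytes or more, and 11 of 100 the 2 of liver or more. For the differences between tissues 18 of 100 splits gave at least the 13 genes of NEMO loss, and all 100 the 0 genes of KEAP1 loss and of double against NEMO knockout. The highest other splits called 1086 genes for the hepatocyte interaction, 482 for that in liver, and 2324, 817 and 259 for the differences between tissues. A split that reverses 1 of the 2 pairs of groups turns the difference of 2 changes into their sum. High counts can therefore arise by construction. Such splits exchange arrays between genotypes of a tissue that differ. For the interactions and the differences between tissues they show neither that chance is excluded nor that it is not.

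The array labelled liver control 3 had NRF2 targets as high as the double knockouts, with a median change of 1.207 over the list against liver controls 1 and 2. NRF2 activity in a liver that kept NEMO is argued against by Ikbkg, at 6.4 on this array and between 6.81 and 7.20 on liver controls 1 and 2 and the KEAP1 knockout livers. This is a weak check of 1 gene on 1 array, as the position of its probes relative to the deleted exons is not given. A swap with an array labelled liver double knockout is argued against as well, because the lowest median change of the NRF2 list over those 3 arrays was 1.218, so no partner is out of place. A single wrong label stays open, and values read after the results were seen go with it. The array correlated most with liver double knockout 2 (r = 0.9943), but nearly as much with KEAP1 knockout liver 1 (r = 0.9933), so this hardly tells these genotypes apart. Its Ikbkg lay within the double knockout livers (6.18 to 6.47). Its cell cycle median of 1.264 lay within theirs too (1.093 to 1.537) and above the KEAP1 knockout livers (0.232 to 0.408). Over 1078 genes of NEMO loss in hepatocytes the array changed by a median of 0.422, above the KEAP1 knockout livers (0.154 to 0.294) and just under the double knockout livers (0.43 to 0.723), so a liver without NEMO and KEAP1 may have been given this label.

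Of 15 male-biased genes 3 were called lower in double than in NEMO knockout hepatocytes. The list had a median of -1.502 and 13 of 15 genes below 0, but was not called with an estimated correlation. A general loss of hepatocyte transcripts as large as that median is argued against by the hepatocyte identity list, whose median change over 22 genes was -0.01. A small loss is not excluded by it. An array of high Xist in the group had the values it needs. Without hepatocyte control 1 and double knockout 3 the median was -0.547, with 11 of 15 genes below 0, so an animal of the other sex may account for part of the list's shift. The 3 called members kept the call there, Slco1a1 at -5.25 against -5.69, Hsd3b5 at -4.77 against -5.32 and Mup3 at -1.44 against -1.99, so their fall does not rest on those arrays. No biological explanation was tested.

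Of endothelial, macrophage and stellate cell markers 15 of 16, 15 of 21 and 16 of 18 were called higher in NEMO knockout than in control cultures. In KEAP1 knockout cultures 15 of 16, 3 of 21 and 4 of 18 were. With an estimated correlation only the stellate list of these was called for NEMO loss, and 0 lists for KEAP1 loss. Cholangiocyte, T and natural killer cell, B cell and neutrophil lists had 0 genes called, with medians from -0.036 to 0.064 for NEMO loss and -0.018 to 0.13 for KEAP1 loss. These 4 lists had at most 2 members above the array median, too few for the test of a lower share of hepatocytes, which took lists with at least 4. For KEAP1 loss, over such members the endothelial list (1.344 ± 0.108) stood 0.917 above the stellate list (0.427 ± 0.137). Here and below ± is an error of the median over genes, not over cultures. This argues only against a lower share of hepatocytes with the other cell types in unchanged proportions. Other cell types that changed unequally in their share were not tested and stay open. For NEMO loss the 3 lists tested moved together, 1.746 for macrophages, 1.728 for stellate cells and 1.572 for endothelium, a gap of 0.174, so a lower share of hepatocytes in those cultures may account for the rise and stays open.

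The same change in the livers is argued against for the endothelial markers, whose median difference between tissues was -0.947 for KEAP1 loss and -1.408 for NEMO loss (-0.742 and -1.153 without the 4 arrays in doubt). It stays open for the stellate markers, at -0.128 ± 0.148 and -0.036 ± 0.247. For the macrophage markers it stays open as well, at -0.521 ± 0.126 and -0.979 ± 0.240, but 0.038 and -0.402 without the arrays in doubt. A change of the cells themselves with genotype was not tested apart from these.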

How the results depend on the processing

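Leaving out the 4 arrays in doubt was chosen after the data were seen, and the other alternatives were planned. Of 293 alternative counts of called genes 174 lay within 1.5 times the reported count and 119 did not. All 72 alternative correlations over genes moved by no more than their jackknife error. That error was computed from the leave-one-out values themselves, 48 of the 72, so for those the outcome was nearly fixed. It was also wide, 0.143 to 0.201 beside correlations of 0.331 to 0.548, so this is a weak check. Of 4483 alternative values of named genes 3755 kept their direction and their side of the threshold, 719 lost the call, 9 gained it and 0 changed direction with a call. Of 712 alternative list results 588 were the same, 109 were weaker, 8 stronger and 7 changed direction without a call. Of the 109 weaker ones 59 came from the estimated correlation, which left 30 of 89 list results the same. A further 38 came from fry, which left 50 of 89 the same and turned the direction of 1. Where a count moved, the cause was not tested, except that the size threshold and smaller fits remove genes or arrays by construction.

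With the replicate number as a block, liver counts were 837 for NEMO loss, 1 for KEAP1 loss, 799 for double against control, 319 for double against NEMO knockout and 4 for the interaction, the hepatocyte interaction had 16 and the tissue difference of NEMO loss 3. With array weights these were 1010, 3, 771, 725 and 9 in liver, 33 for the hepatocyte interaction and 28 for the tissue difference, with 845 for double against KEAP1 knockout hepatocytes and 2 for the tissue difference of double against NEMO knockout. With all 24 arrays in one fit liver counts were 779, 5, 632 and 442 for the first 4 comparisons and 2 for double against KEAP1 knockout, and in hepatocytes 259 for double against KEAP1 knockout and 5 for the interaction. With only the groups compared, liver counts were 26 for NEMO loss, 0 for double against control, 333 for double against NEMO and 2 for double against KEAP1 knockout. Hepatocyte counts were 155 for KEAP1 loss and 1150 for double against control, and control hepatocytes against liver had 300. Without the arrays in doubt liver counts were 2265, 990, 1732, 651, 10 and, for the interaction, 65, the hepatocyte interaction had 22, the tissue differences of KEAP1 loss and of double against NEMO knockout 2 and 3, and control hepatocytes against liver 576. With a change of at least 1 as well, counts were 134 and 92 in liver for NEMO loss and double against NEMO knockout, 526, 168, 710, 195 and 256 in hepatocytes for NEMO loss, KEAP1 loss, double against control, against NEMO and against KEAP1 knockout, and 506 between the controls. Without an intensity trend KEAP1 loss in hepatocytes had 232 and the interaction 3, and with a filter on dim probe sets the latter had 20.

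Leaving out each array in turn gave liver counts of 23 to 1409 for NEMO loss, 0 to 497 for KEAP1 loss, 0 to 2207 for double against control, 16 to 175 for double against NEMO knockout, 0 to 2 for double against KEAP1 knockout and 2 to 14 for the interaction. In hepatocytes they were 807 to 1196, 123 to 405, 1042 to 1946, 293 to 530, 157 to 571 and 0 to 72. Tissue differences gave 0 to 47 for NEMO loss, 0 to 5 for KEAP1 loss and 0 to 1 for double against NEMO knockout, and the controls 638 to 964. Correlations ranged from 0.348 to 0.485 for KEAP1 loss and 0.372 to 0.599 for NEMO loss in liver, and from 0.238 to 0.431 and 0.391 to 0.543 in hepatocytes. Over all group pairs, residuals of arrays with the same replicate number had r above 0.1 in 11 of 18 pairs in liver (-0.054 to 0.258) and 6 of 18 in hepatocytes (-0.352 to 0.215). All 3 pairs passed for liver control with liver double knockout and in none of the other 11 group pairs. In that group pair 5 of the 6 arrays were closest to their own number, and so were 5 of 6 for KEAP1 with NEMO knockout livers. In liver double knockout against control the block changed the count of called genes, and not the call of Angptl8 or of the 3 lists named. The number is not shown to pair the arrays in any group pair, and in none were all 6 arrays closest to their own number. Signal over background limits dim genes, where changes are understated.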

Other observations

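No hypothesis beyond those above was tested. Some transcripts stood apart on single arrays. Liver double knockout 3 had Retn at 8.87, Cidea at 6.69 and Krt19 at 7.29. Hepatocyte control 1 and double knockout 3, the arrays of high Xist, had the female-predominant Cyp2b13 at 9.33 and 8.78, Sult3a1 at 11.2 and 8.74, and A1bg at 9.91 and 4.26.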
